A study of Drosophila melanogaster with 66 samples.

How the data were processed

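Total RNA of whole adult flies of Drosophila melanogaster was measured on 66 Affymetrix 3' IVT arrays in 20 groups. Each group held 3 arrays, except the F2 males and both sexes of F3, whose groups held 4. The deposited values are log2 GCRMA expression levels, 1 per probe set and array. The submitters' processing notes name GCRMA without a version and limma 3.46.0, and do not say what limma was used for. The lowest value on every array was 2.2305 and the highest on any array 15.736. Levels near 2.23 were treated as the floor of the scale, so that a fold against a group at the floor is a lower bound. Arrays carry no count depth, and their number limits the precision.

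The table held 18952 probe sets. The 183 control probe sets were left out and 18769 kept. Of these, 13647 were paired with 1 gene symbol, 402 with several genes and 4720 with none. The Entrez identifiers of 13544 of the 1-gene probe sets were found in the RefSeq gene table, which changed 0 symbols. Each of the 1094 genes with more than 1 probe set was represented by the probe set with the highest mean over all arrays, which left 17104 entries, 11982 of them with a symbol. An entry was tested in a sex if it exceeded the 40th percentile of that sex's values in at least 3 arrays (2.5057 in females, 2.6348 in males). This left 12809 entries in females, 11357 in males and 13281 in the fit of both sexes.

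Differences were estimated with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8) by limma's moderated test. All groups of a sex were fitted together with the labelled batch (4 batches) as a factor, which left 19 residual degrees of freedom in females and 21 in males. Differences between the sexes came from 1 fit of all 66 arrays with 43 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all entries tested in that comparison. Values are given as log2 change ± standard error from the fit, and levels as mean ± SD of the arrays. A fold is the difference between group means of the log2 levels put on the linear scale, which is a ratio of geometric means. The design text describes biological replicates, so the p-values measure the spread between arrays of biological replicates. How the replicates were raised was not analysed here, and residuals of arrays with the same number correlate in most comparisons. Intervals are 95% intervals of the fit.

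Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. The 21 lists covered insulin-like peptides, insulin and TOR signalling, lipid turnover, glycolysis and sugar storage, digestive enzymes, oxidative phosphorylation, cytosolic ribosomal proteins, innate immunity, heat shock, detoxification, yolk with eggshell and ovary, testis, male accessory gland, eye, muscle, fat body, neuropeptides, the circadian clock, Polycomb with trithorax, the piRNA pathway and Y-linked genes. Chromosome arms of called genes were compared with those of all genes tested by Fisher's exact test, two-sided, adjusted over arms. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

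The groups, comparisons, gene lists, thresholds and the rule for naming genes were set before the data were examined. The rule names Ilp2, Ilp3, Ilp5, rpr and w wherever measured. In the founders, the F1 flies with both constructs, F2 and F3, it names the 5 largest rises and 5 largest falls among called genes whose test arrays all lay on one side of the control mean. It adds the 3 called genes of smallest p in each of the 6 lists with the largest called share. Where a comparison had no call, the 3 genes of smallest p in each direction are named as not passing. Each sibling genotype and the interaction contribute 3 rises and 3 falls, and each sex difference its 3 smallest adjusted p-values.

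Alternatives set beforehand were no batch term, the replicate number as a block beside batch, only the compared groups without a batch term, no filter, a filter at the 60th percentile, every probe set tested, quantile normalization within a sex, both sexes in 1 fit, an estimated correlation for the lists, and leaving out each array in turn. Further alternatives were chosen after the data were seen. These were F0 and F1 arrays only, batches numbered separately in the F0 and F1 arrays and in the F2 and F3 arrays, the F2 female pair numbered 2 or the F2 male pair numbered 3 left out, the F2 and F3 arrays numbered 3 left out, and for F2 and F3 the compared groups alone with the replicate block. The tests were tried on simulated data. With 200 changed genes per comparison, at most 8 other genes were called, and a shifted list was called in 16 of 16 simulations beside 1 of 312 unshifted lists. Noise was drawn independently for each gene and array, without correlated genes, batch differences or pairing by number. These simulations therefore check the procedure and do not measure false calls or recovery on the real arrays. Ilp3, rpr and w were not analysed here.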

Results

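Whole-body transcripts of adult flies were profiled over 4 generations that descend from founders whose insulin-producing brain cells had been ablated genetically. The founders (F0 test) carried a driver active in these cells, ilp3-GAL4, on the third chromosome and the cell-death gene reaper under UAS control, UAS-rpr, on the second. Each was held over a fluorescent balancer, a multiply inverted chromosome: Ser-GFP (ser) opposite the driver (dilp3) and CyO-YFP (cyo) opposite UAS-rpr (rpr). Founder males crossed to w1118 females gave 4 kinds of F1 siblings, carrying both constructs, rpr with ser, cyo with dilp3, or cyo with ser. Only the siblings with both constructs combine driver and cell-death gene. F1 males with rpr and ser gave F2 offspring free of balancers, and F2 test males gave F3. F2 and F3 test flies carried none of the constructs, so differences from their controls ask what descent from ablated founders leaves behind.

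The data comprised 66 arrays in 20 groups, 10 in each sex. Founders, the F1 control, each F1 sibling genotype and the F2 females had 3 arrays per group and sex. F2 males and F3 flies of both sexes had 4 arrays in each of the control and test groups. The labels name the w1118 F1 control as the control of both the founders and the F1 siblings, so these comparisons share their control arrays, and founders and siblings carry constructs and balancers that the control lacks. The design text speaks instead of a founder control and of unprofiled F1 controls. Median log2 levels ranged from 3.25 to 4.16 on the F0 and F1 arrays and from 3.30 to 4.50 on the F2 and F3 arrays. Between 3447 and 4532 probe sets lay at the lowest value on F0 and F1 arrays, against 4663 to 5575 on F2 and F3 arrays, so groups are compared within these sets only. The fit of a sex still pools both sets with a shared batch term and spread. F2 and F3 arrays therefore also shape the founder and F1 estimates. No batch held 2 arrays of each group in any comparison of founders or F1 siblings with the control, too few for a value within batch. In females, the arrays of rpr with ser and of cyo with dilp3 lay in batches 3 and 4 and the F1 control arrays in batches 1 and 2, so these comparisons shared no batch.

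The peptides of the ablated cells gave little signal in whole flies. Ilp2, an insulin-like peptide of the brain's insulin-producing cells, averaged 2.87 ± 0.31 (log2, SD, n = 3) in founder females and 3.23 ± 0.29 in control females, a log2 change of -0.30 ± 0.28 with limma's adjusted p = 0.844. In founder males the change was -0.18 ± 0.39 (adjusted p = 0.926). Ilp5, made by the same cells, lay between 2.34 and 3.01 in every group mean, near the floor of 2.23. None of the 4 insulin-like peptides measured in females or the 3 in males was called in any comparison with a control. Loss of the cells was therefore not measurable through their own transcripts at this signal.

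Founder females differed from control females in a serine protease gene, a maltase gene and several detoxification genes. Ser12, a serine protease gene on arm 2L, lay at the floor in all 3 control arrays and reached 8.0 ± 0.21 in founders, at least 54.6-fold higher, with a fitted change of 6.33 ± 0.79 (adjusted p = 6.4e-05). CG11893 on 3R, of the ecdysteroid kinase-like family, rose by 5.46 ± 0.81 (adjusted p = 0.000616; 2 of 3 control arrays lay near the floor), the drosomycin-like peptide gene Drsl2 by 4.73 ± 0.71 (0.000652) and the UDP-glycosyltransferase gene Ugt303B1 by 3.72 ± 0.48 (8.7e-05). Mal-B1, a maltase gene, fell from 9.59 ± 1.38 to 4.60 ± 1.07, 31.8-fold lower (adjusted p = 0.00117). The mitochondrial cytochrome P450 gene Cyp12d1-d fell from 9.08 ± 0.56 to 4.07 ± 0.88, at least 32.4-fold lower with 1 founder array at 3.07 (adjusted p = 0.00136). CG43074 changed by -5.17 ± 0.66 (adjusted p = 8.7e-05) and CG8654 by -3.94 ± 0.30 (adjusted p = 1.4e-07). In each of these 8 genes the 3 founder arrays lay beyond all 3 control arrays, as in 98 of the 106 genes called. By chance 3 arrays lie beyond 3 others in 10% of genes, and calling favours such genes, so this separation is no independent support. The remaining genes named by the rule were CG18563, which rose by 3.85 ± 0.82 (adjusted p = 0.0198), and CG10514, which changed by -4.31 ± 0.90 (0.0177). Each call was lost when any of 4 of the 6 arrays was left out, with adjusted p of up to 0.147 and 0.15 (without founder array 1).

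Among the detoxification enzymes 5 rose and 6 fell of 135 measured in founder females, and 16 were called when adjusted over the list alone. The glutathione transferase gene GstE11 rose by 1.61 ± 0.17 (adjusted p = 4.1e-06), its relative GstE6 changed by -1.22 ± 0.13 (1.0e-05), and Cyp6g1, a P450 gene known from DDT resistance, changed by -2.60 ± 0.31 (2.7e-05), in 3 of 3 arrays each. Of 18 fat-body and carrier genes 2 rose and 1 fell, 5 when adjusted over the list alone. The clotting factor gene Hml rose by 2.58 ± 0.43 (adjusted p = 0.00194) and the lipocalin gene GLaz by 1.57 ± 0.32 (0.0144), while the storage protein gene Lsp2 changed by -3.42 ± 0.81 (0.0486), with 2 of 3 founder arrays below all controls. The call of Lsp2 was kept in 5 of 17 alternatives, with adjusted p between 0.000893 and 0.992, and that of GLaz in 10 of 17, between 5.2e-05 and 0.436. Without founder array 1 the adjusted p of Lsp2 was 0.274, and without control array 3 that of GLaz was 0.169. Innate immunity genes leaned upward, 23 of 34 with a positive change and 1 called, 6 when adjusted over the list alone (camera adjusted p = 0.000471, and 0.877 with an estimated correlation, as for the other 3 lists called). Glycolysis and sugar storage leaned downward, with 5 of 26 positive, 1 called and 5 adjusted over the list alone (0.000471), as did neuropeptides with 5 of 29 positive and 0 called (0.0152). Yolk, eggshell and ovary genes leaned upward, 34 of 37 positive with a median of 1.08 and 0 called (2.2e-05). With the replicate block the last 3 had 0.362, 0.787 and 1.

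In total 106 genes were called in founder females, 51 higher and 55 lower, and 1153 had an unadjusted p under 0.05. The count was 418 with the replicate block, 63 without the batch term, 28 with F0 and F1 arrays only and 1, Ser12, with the compared groups alone. It was 59 without control array 3 and 165 without founder array 3. Ser12 was called in all 17 alternatives (adjusted p at most 0.00976). CG8654, GstE11, GstE6, Cyp6g1, CG11893 and Ugt303B1 were called in 16 of 17, all but the fit of the compared groups alone, where their adjusted p ranged from 0.065 to 0.239.

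Founder males shared the fall of Cyp12d1-d and Mal-B1 and the rise of Drsl2. Cyp12d1-d fell from 10.52 ± 0.49 to 3.51 ± 0.78, at least 128-fold lower since 2 founder arrays shared the value 3.06 (-7.09 ± 0.77, adjusted p = 2.2e-06), and Mal-B1 was 27.8-fold lower (-4.59 ± 0.90, 0.00331). The lipase gene CG6295 was 44.3-fold lower (-5.11 ± 0.72, 8.8e-05), and CG12934 changed by -4.79 ± 0.76 (0.000387). CG12692 on the X chromosome fell from 6.92 ± 0.45 to near the floor, at least 25.6-fold lower (adjusted p = 5.1e-05). Drsl2 rose 37.7-fold, from 3.72 ± 0.30 to 8.95 ± 0.35 (adjusted p = 8.3e-05), whereas its relative Drsl4 changed by -2.41 ± 0.51 (0.00621). CG10725, which encodes a chitin-binding protein, rose from the floor to 7.21 ± 1.03, at least 31.6-fold higher (adjusted p = 5.0e-06). All 3 founder arrays lay beyond all controls in each, as in 354 of the 390 genes called. Also named by the rule were CG32198 (4.50 ± 1.02, adjusted p = 0.0114), CG14957 (4.22 ± 1.17, 0.0443; 2 of 3 control arrays near the floor) and CG18563 (4.02 ± 0.86, 0.00681). CG14957 lost its call whichever of the 6 arrays was left out, with an adjusted p of 0.178 without founder array 3. CG32198 lost its call when either of 2 of the 6 arrays was left out (up to 0.105), and CG18563 without founder array 1 (0.0633).

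Of 128 detoxification enzymes measured in males 8 rose and 15 fell in founders, 32 when adjusted over the list alone. The neighbouring P450 genes Cyp6g1 and Cyp6g2 changed by -2.10 ± 0.26 and -2.06 ± 0.25 (both adjusted p = 1.2e-05). Of 39 digestive enzymes 1 rose and 6 fell, 10 adjusted over the list alone, and the list leaned downward (camera adjusted p = 0.0139, and 0.949 with an estimated correlation). The gut protease genes Jon25Bi and Jon25Bii changed by -3.04 ± 0.50 (adjusted p = 0.000611) and -4.15 ± 0.74 (0.00144), while Ser6, another, rose by 3.30 ± 0.60 (0.00163). In the male accessory gland and ejaculatory duct list 1 gene rose and 2 fell of 36, 3 adjusted over the list alone. The ejaculatory bulb protein genes EbpII and Ebp changed by -2.04 ± 0.47 (adjusted p = 0.0137) and -2.13 ± 0.51 (0.0188), and Dup99B, a relative of the sex peptide gene, rose by 1.31 ± 0.34 (0.03). In the fat-body list NLaz, another lipocalin gene, changed by -0.95 ± 0.21 (0.0088), and in the lipid turnover list Lpin, which encodes the phosphatidate phosphatase lipin, rose by 0.45 ± 0.12 (0.0434). Of 45 Polycomb and trithorax genes 3 fell, 3 adjusted over the list alone: the histone chaperone gene Caf1-55 (-1.14 ± 0.30, 0.0319), Jarid2 of Polycomb repressive complex 2 (-0.57 ± 0.16, 0.0456) and the deacetylase gene HDAC1 (-0.92 ± 0.26, 0.0478). All founder arrays lay beyond all controls in these genes, yet the calls near the threshold moved. Leaving out a single array gave an adjusted p of up to 0.236 for Caf1-55, 0.169 for Jarid2 and 0.105 for Ebp (each without founder array 3), 0.2 for HDAC1 and 0.155 for Dup99B (each without control array 2), and 0.206 for Lpin (without control array 3). For EbpII it reached 0.0726 (without founder array 3) and for NLaz 0.0805 (without control array 2). Jarid2 was called in 5 of 17 alternatives, HDAC1 in 6, Lpin in 7 and Caf1-55 in 8.

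In total 390 genes were called in founder males, 139 higher and 251 lower, and 1659 had an unadjusted p under 0.05. Quantile normalization called 392 and split them into 189 higher and 203 lower. The count was 109 with F0 and F1 arrays only, 49 with the compared groups alone, 251 without founder array 3, and 231 and 235 without control arrays 1 and 2. Cyp12d1-d, CG10725, CG12692, CG6295, CG12934 and Cyp6g1 were called in all 17 alternatives (adjusted p at most 0.0369). Arm 2L, which carries part of the balanced second chromosome, held 86 of the 336 called genes with a known arm, or 25.6% against 19.0% of those tested (Fisher's exact test, adjusted p = 0.0202). Of the oxidative phosphorylation genes 2 of 74 fell, of the eye list 1 of 22 fell, and of the circadian clock list 1 of 13 rose. In simulated data at these array numbers, 66.7% of genes changed by 2 log2 units were recovered in founder females and 87.9% in founder males, against 22.4% and 40.3% of genes changed by 1.

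**Figure D1:**
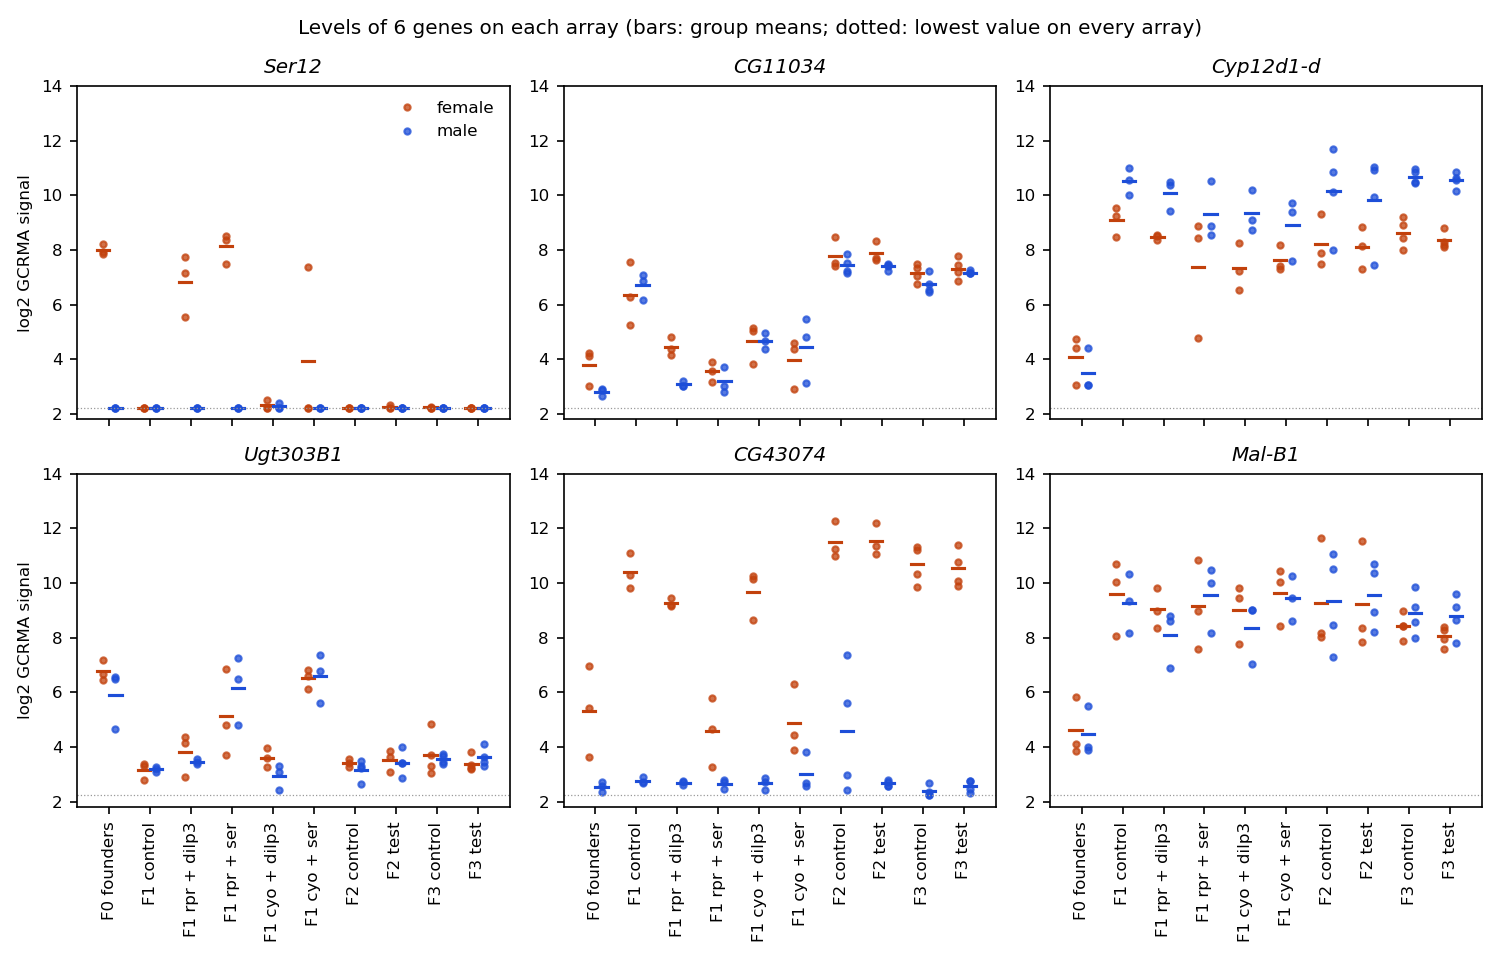
Log2 GCRMA level of 6 genes on each array (points), by group and sex. Ser12 lies at or near the floor in all males and in F2 and F3, and Cyp12d1-d lies lower in the founders than in the F1 control.

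The founder effect differed between the sexes in 16 genes, 5 with the male effect higher and 11 lower (659 at unadjusted p under 0.05). The largest was in Ser12, at the floor in all founder and control males (male minus female effect -6.08 ± 0.78, adjusted p = 1.4e-06). CG15239 reached 6.10 ± 0.49 in founder males and 2.50 ± 0.47 in founder females from the floor in both controls (3.56 ± 0.29, adjusted p = 5.3e-12). COX6AL2, a relative of a cytochrome oxidase subunit gene, fell in males from 8.29 ± 0.52 to 5.37 ± 0.43 (-2.67 ± 0.32, adjusted p = 3.1e-07). Quantile normalization called 20 (9 and 11), the replicate block 79 and the compared groups alone 8. Without male founder array 1 or female control array 1 the count was 25, and without female founder array 2 or 3 it was 31.

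F1 females with both constructs, like the founders, had high Ser12 and CG11893. Ser12 reached 6.82 ± 1.14 against the floor in controls, at least 24.1-fold higher (4.84 ± 0.76, adjusted p = 0.00717), and CG11893 rose by 4.31 ± 0.78 (0.0238). Atg5, an autophagy gene on the X chromosome, rose from 4.33 ± 0.32 to 7.14 ± 0.26 (2.84 ± 0.34, adjusted p = 0.000196). It was also called in each sibling genotype that cannot ablate the cells, at 7.01 with cyo and dilp3, 6.73 with cyo and ser and 6.52 with rpr and ser (adjusted p = 0.000446, 0.000564 and 0.0031). CG34040 rose by 2.54 ± 0.46 (0.0238; its other probe set changed by 0.60) and plum, an immunoglobulin-superfamily gene, by 2.53 ± 0.41 (0.0101), while CCDC53 of the actin-regulating WASH complex changed by -1.57 ± 0.29 (0.0268). In each, 3 of 3 arrays lay beyond all controls, as in all 15 genes called. Atg5 was called in 16 of 17 alternatives, all but the compared groups alone (0.305). Without test array 2 the adjusted p was 0.0906 for Ser12, 0.235 for CG11893, 0.141 for plum and 0.188 for CCDC53, and without control array 3 it was 0.175 for CG34040. In total 15 genes were called, 13 higher and 2 lower, with 579 at unadjusted p under 0.05. The count was 27 with the replicate block, 3 with F0 and F1 arrays only, 0 with the compared groups alone, 3 without test array 1 and 7 without test array 2. Digestive enzymes (27 of 40 positive, 0 called, 2 adjusted over the list alone) and muscle genes (21 of 24 positive, 0 called) leaned upward, both at camera adjusted p = 0.00131. These and the other 2 lists called, detoxification and yolk, had adjusted p = 0.81 with an estimated correlation.

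F1 males with both constructs had low CG11034, which fell from 6.71 ± 0.48 to 3.08 ± 0.09, 12.3-fold lower (-3.55 ± 0.34, adjusted p = 3.1e-06). CG11034 was the gene named here that kept its call whichever array was left out, and it was called in 16 of 17 alternatives (0.14 in the compared groups alone). The mucin gene Muc68E rose by 3.06 ± 0.63 (0.0424), CG18404 by 2.33 ± 0.38 (0.00564), CG17571 by 1.93 ± 0.41 (0.0424), CG11891 by 1.88 ± 0.40 (0.0424) and the P450 gene Cyp310a1, at the floor in controls, by 1.76 ± 0.33 (0.0201), at least 3.26-fold. The methuselah-like receptor gene mthl8 changed by -1.88 ± 0.30 (0.00446; -0.78 in its other probe set), CG2065 by -1.82 ± 0.32 (0.00929), the D-amino acid oxidase gene Daao2 by -1.40 ± 0.29 (0.0424) and the microtubule gene Map205 by -1.29 ± 0.22 (0.00888). In the detoxification list 2 rose and 1 fell of 128, 5 adjusted over the list alone, with GstE11 at 1.2 ± 0.23 (0.0201) and Cyp6g2 at -1.15 ± 0.25 (0.0486). Leaving out a single array gave an adjusted p of up to 0.441 (Cyp6g2, test array 3), 0.374 (CG17571, control array 2), 0.369 (CG11891, test array 1), 0.306 (Muc68E, test array 1), 0.29 (Daao2, control array 1), 0.232 (Cyp310a1, test array 1) and 0.169 (GstE11, test array 1). It stayed at or below 0.0821 for Map205 and CG2065 (control array 2), mthl8 and CG18404 (test array 3). In total 25 genes were called, 13 higher and 12 lower (625 at unadjusted p under 0.05). The count was 3 with F0 and F1 arrays only, 0 with the compared groups alone, 10 and 2 without test arrays 1 and 3, and 13 and 12 without control arrays 2 and 3. Oxidative phosphorylation genes leaned upward, 69 of 74 positive with a median of 0.31, 0 called and 1 adjusted over the list alone (camera adjusted p = 9.3e-10, and 0.968 with an estimated correlation).

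The change of F1 flies with both constructs against the control differed between the sexes in 8 genes, 2 higher and 6 lower (314 at unadjusted p under 0.05), including Ser12 (-4.76 ± 0.77, adjusted p = 0.00104), which stayed at the floor in males, and Atg5 (-2.50 ± 0.41, 0.00106). By the cross, F1 test females carried an X chromosome of the founder line, and F1 test males only that of their w1118 mothers. By itself this sex difference therefore does not separate the constructs from the X, on which Atg5 lies. Atg5 was, however, also called in females with cyo and ser, which carry neither construct. The count of genes that differed between the sexes was 14 with the replicate block and 0 with the compared groups alone. Without male test array 2 or 3 it was 5 and 4, without male control array 3 it was 4, and without female test array 1 or 2 it was 5.

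Siblings that cannot ablate the cells, because they lack driver, cell-death gene or both, carried some of the same changes. Females with cyo and ser had Ugt303B1 at 6.51 ± 0.36 (3.30 ± 0.46, adjusted p = 0.00104) and CG43074 at 4.88 ± 1.27 against 10.40 ± 0.66 in controls (-5.82 ± 0.64, 4.3e-05). CG11893 rose by 5.03 ± 0.79 (0.00378) and Drsl2 by 3.70 ± 0.69 (0.0173), while CG11034 changed by -2.67 ± 0.48 (0.0128) and CG8654 by -1.962 ± 0.29 (0.00188). These 6 calls were lost in the compared groups alone (adjusted p from 0.457 to 0.974). Leaving out sibling array 1 gave 0.152 for Drsl2, 0.153 for CG11034 and 0.0603 for CG11893. Ser12 reached 7.36 in sibling array 1 and lay at the floor in the other two. Whether that sample held flies of a single genotype was not tested, and its values enter the results with cyo and ser and the contrasts between siblings. In total 23 genes were called, 16 higher and 7 lower (868 at unadjusted p under 0.05). The count was 632 with the replicate block, 3 with F0 and F1 arrays only, 46 and 72 without sibling arrays 2 and 3, and 14 without control array 3. Innate immunity genes leaned upward, 26 of 34 positive with 1 called and 3 adjusted over the list alone (camera adjusted p = 1.5e-07, and 0.477 with an estimated correlation).

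Females with rpr and ser had Ser12 at 8.13 ± 0.56, at least 59.6-fold higher (6.53 ± 0.96, adjusted p = 0.00143), and CG43074 at 4.57 ± 1.26 (-7.34 ± 0.81, 0.000122). Except for CG11893, the other genes named by the rule had fitted changes well beyond the differences between group means. The NADPH oxidase gene Nox had a fitted change of 4.02 ± 0.85 (0.0109; 0.18 in its other probe set, near the floor) at means of 5.19 and 3.61, the cathepsin gene CtsL3 of -5.36 ± 1.04 (0.0071) at 3.50 and 5.85, and CG4962 of -5.27 ± 1.27 (0.0182) at 3.53 and 5.12, whereas CG11893 had 3.29 ± 0.99 (0.0437) at 6.56 and 2.65 and was called in 7 of 17 alternatives (0.0163 to 0.944), with 0.124 when control array 2 was left out. In females with cyo and dilp3 the aurora kinase gene aurB had 4.30 ± 0.78 (0.00212) at means of 6.50 and 5.50, the condensin gene Cap-D2 4.46 ± 1.22 (0.0172), trk 4.14 ± 0.89 (0.00588), CG4962 -5.26 ± 1.27 (0.00972), sas -4.09 ± 0.79 (0.00309) at 3.98 and 4.67, and Shrm -3.82 ± 0.52 (0.000446; -1.44 and -0.33 in its other probe sets). Without the batch term none of Nox, CtsL3, CG4962, aurB, Cap-D2, trk, sas and Shrm was called, with adjusted p from 0.641 to 1, while Ser12 and CG43074 still were. Altogether 1095 genes were called with rpr and ser (489 higher, 606 lower, 3800 at unadjusted p under 0.05) and 2614 with cyo and dilp3 (1495 higher, 1119 lower, 4836 at unadjusted p under 0.05). Without the batch term these counts were 21 and 15, with the replicate block 558 and 85, and with F0 and F1 arrays only 0 and 0. Without control array 2 they were 155 and 729, without control array 1 the first was 1846, and without array 3 of cyo with dilp3 the second was 1448. Quantile normalization called 1564 with rpr and ser, 929 higher and 635 lower. Among the genes called, 64.3% and 75.9% had a difference of group means of the fitted sign, and the median absolute change was 1.62 and 1.61 fitted against 0.26 and 0.19 between means. The list of yolk, eggshell and ovary genes carried many calls, 23 higher of 37 with rpr and ser and 30 higher and 1 lower with cyo and dilp3 (32 and 35 adjusted over the list alone; camera adjusted p = 6.0e-17 and 2.6e-15, and 0.566 and 0.463 with an estimated correlation). With the replicate block these lists had adjusted p = 0.53 and 0.935. The levels themselves showed no clear rise. The median of the list was 9.93, 8.47 and 11.21 on the arrays with rpr and ser and 10.62, 9.62 and 10.82 with cyo and dilp3. On the control arrays it was 10.83, 9.09 and 11.64.

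In males the siblings without ablation shared the fall of CG11034. It changed by -3.52 ± 0.33 with rpr and ser (11.5-fold lower, adjusted p = 1.9e-06) and by -2.03 ± 0.33 with cyo and dilp3 (0.00798), each in 3 of 3 arrays. Ugt303B1 rose by 2.98 ± 0.49 with rpr and ser (0.00272) and by 3.50 ± 0.50 with cyo and ser (0.000486), and Drsl2 by 3.21 ± 0.69 (0.0271) and 4.49 ± 0.71 (0.00185). With rpr and ser CG18563 rose by 4.08 ± 0.83 (0.0168), CG4210 changed by -2.28 ± 0.51 (0.0334) and CG33287 by -2.19 ± 0.31 (0.000493). With cyo and dilp3 Muc68E rose by 2.91 ± 0.61 (0.0414), the prolyl hydroxylase gene PH4alphaNE3 by 2.22 ± 0.49 (0.0477) and CG18404 by 2.03 ± 0.37 (0.0126), while CG31674 changed by -1.65 ± 0.35 and CG10621 by -1.59 ± 0.34 (both 0.0414). With cyo and ser Muc68E rose by 2.99 ± 0.63 (0.0306), and CG6295 (-3.15 ± 0.71, 0.0476), CG34029 (-2.45 ± 0.45, 0.0108) and CG4210 (-2.34 ± 0.52, 0.0422) fell. CG11034 with rpr and ser and CG33287 were called in 16 of 17 alternatives, and all calls of this paragraph were lost in the compared groups alone (adjusted p from 0.194 to 0.729).

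Counts in these males were 55 with rpr and ser (31 higher, 24 lower, 892 at unadjusted p under 0.05), 32 with cyo and dilp3 (16 and 16, 679) and 45 with cyo and ser (21 and 24, 1030). Quantile normalization split the 32 into 20 and 12. The replicate block gave 238, 145 and 470 genes, F0 and F1 arrays only 14, 2 and 7, and the compared groups alone 0 in each. For rpr with ser the count was 28 without sibling array 2 or control array 3. For cyo with dilp3 it was 12 and 3 without sibling arrays 2 and 3, 15 without control array 1 and 9 without control array 2 or 3. For cyo with ser it was 26 and 16 without control arrays 1 and 3. Drsl2 in rpr with ser lost its call when any of 4 of the 6 arrays was left out, and fell to 1.98 without sibling array 1 (adjusted p = 0.178). CG6295 and CG4210 in cyo with ser lost theirs when any of 5 of 6 was left out (up to 0.259 and 0.251, called in 6 and 7 of 17 alternatives), as did CG4210 in rpr with ser (up to 0.176). Muc68E in cyo with ser and CG18404 in cyo with dilp3 also lost theirs in 5 of 6 (up to 0.186 and 0.101), CG18563 in rpr with ser in 4 of 6 (0.113), and CG11034 in cyo with dilp3 and CG34029 in cyo with ser in 2 of 6 (0.0511 and 0.0985). Muc68E in cyo with dilp3, PH4alphaNE3, CG31674 and CG10621 lost their calls whichever array was left out, with adjusted p of up to 0.173, 0.264, 0.187 and 0.222. Genes with a known arm lay on chromosomes 2 and 3 in 44 of 46, 27 of 27 and 38 of 39 calls, against 83.7% of those tested. The testis list leaned downward with cyo and ser (3 of 39 positive, 0 called; camera adjusted p = 0.000119, and 0.997 with an estimated correlation).

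The interaction asks what driver and cell-death gene do together beyond the sum of each alone. In males no gene passed limma's test (0 called, 392 at unadjusted p under 0.05, smallest adjusted p = 0.622, 9 called with the replicate block). The genes of smallest p, none passing, were the phosphatase gene Fcp1 (1.58), CG9795 (1.35), CG6403 (1.24), fs(1)K10 (-1.78), Dap160 (-1.48; its other probe set changed by 0.24) and CG11262 (-2.06). In females 3982 genes were called, 2016 higher and 1966 lower (5576 at unadjusted p under 0.05), led by the cuticle gene pot (8.61 ± 1.37, adjusted p = 0.000611), the flight-muscle actin gene Act88F (7.91 ± 1.92, 0.00576), sas (7.54 ± 1.23, 0.00065) and the eggshell genes Cp19 (-16.07 ± 2.58, 0.000632), Cp16 (-15.54 ± 2.58, 0.000748) and Cp18 (-14.13 ± 2.81, 0.00202). Without the batch term 0 were called and Cp19, Cp16 and Cp18 turned positive (0.98, 1.64 and 2.17). The count was 41 with the replicate block and 0 with F0 and F1 arrays only. Of the genes called, 64.3% had a difference of group means of the fitted sign, and the median absolute change was 2.63 fitted against 0.25 between means. The yolk, eggshell and ovary list had 31 lower and 1 higher of 37, 36 adjusted over the list alone (camera adjusted p = 4.5e-13, and 0.467 with an estimated correlation).

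Siblings differed among themselves, in the fit without the replicate block, mainly in genes of the chromosome that they inherited in different forms. This contrast between siblings does not take the control as its reference, although all arrays of a sex enter the fit, and was added after the comparisons above. Between rpr and cyo siblings 26 genes were called in males and 30 in females, and of those with a known arm 18 of 19 (94.7%) and 22 of 24 (91.7%) lay on chromosome 2, against 39.6% and 38.9% of genes tested (Fisher's exact test, adjusted p = 6.6e-07 and 2.0e-07). Between dilp3 and ser siblings 106 and 24 were called, and 85 of 96 (88.5%) and 19 of 19 (100%) lay on chromosome 3, against 44.1% and 44.6% (3.9e-19 and 2.8e-07). Named genes include Ugt303B1 on 3R, lower by -3.22 with dilp3 than with ser in males, CG43074 on 3L, higher by 5 with dilp3 in females, and Ser12 on 2L, higher by 4.31 with rpr than with cyo in females. They were chosen after their values were seen. With the replicate block 85.4% and 90% of calls between rpr and cyo siblings lay on chromosome 2, but for dilp3 against ser 799 and 1955 genes were called and the shares on chromosome 3 were 57.9% and 47.7%. F0 and F1 arrays only called 0 and 28 genes in males and 3 and 6 in females.

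**Figure D2:**
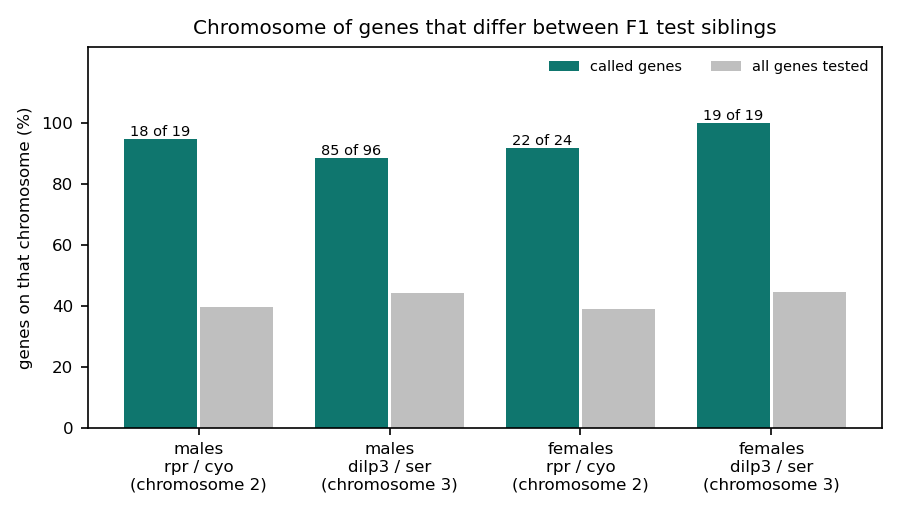
Percent of genes on the chromosome by which the F1 siblings differ, among genes called without the replicate block and among all genes tested, by sex. Called genes lie there in 88.5% to 100% of cases, genes tested in 38.9% to 44.6%.

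Transcripts of the sex organs checked the sex labels. The median level of the testis list was at least 8.01 on every male array and at most 3.23 on every female array. The F2 male control array 3 also carried female transcripts, with a mean yolk protein level of 12.54 against 2.86 to 3.17 in the other 3 arrays of its group. The F2 female control and test arrays numbered 2 lacked the eggshell transcript Cp36 or had less of it (2.77 and 8.18 against 13.61 to 13.95 on the other F2 female arrays), and had more Act88F (14.37 and 14.01 against 11.32 to 12.70).

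**Figure D3:**
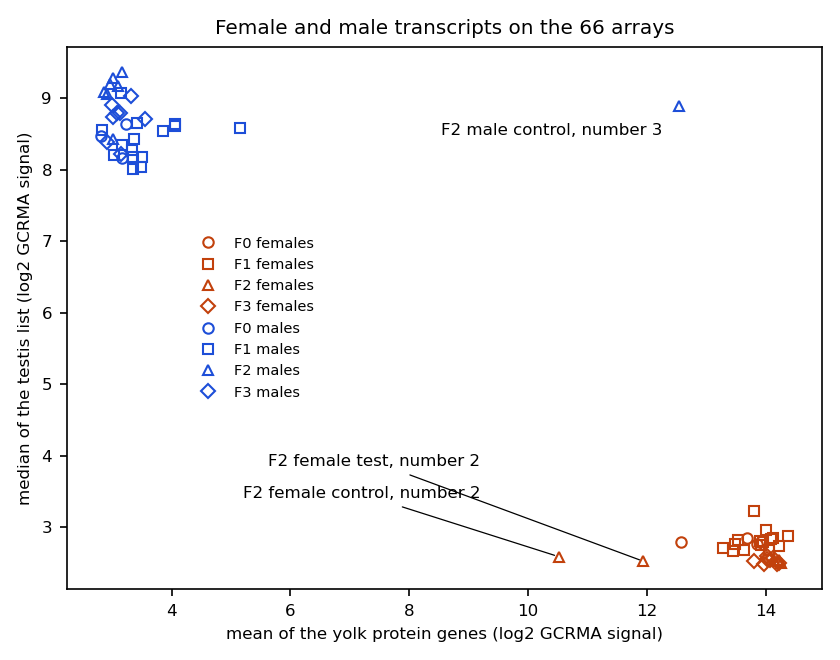
Mean log2 level of the yolk protein genes against median log2 level of the testis list, 1 point per array. Male and female arrays separate along the testis axis, and F2 male control array 3 lies at a yolk level of 12.54.

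In the second generation after the founders no gene was called between test and control flies of either sex. F2 females had 0 calls in limma and 20 genes at unadjusted p under 0.05, and F2 males 0 and 97. Both counts lay far below a 0.05 share of the 12809 and 11357 entries tested, so this fit was conservative. It ignores the pairing of test and control arrays by number, whose residuals correlated at 0.924 to 0.97 in F2 females and 0.297 to 0.893 in F2 males. The genes of smallest p, all at adjusted p = 1, were in females the glutathione transferase gene GstD7 (0.53 ± 0.17), tilB (0.49 ± 0.17), MFS1 (0.86 ± 0.33), side-VII (-0.66 ± 0.25), CG6012 (-0.56 ± 0.22) and Ipk1 (-0.47 ± 0.19). In males they were the cuticle gene TwdlT (0.71 ± 0.23), CG31041 (0.74 ± 0.26), Rgk1 (0.42 ± 0.16; its other probe set, at the floor, changed by 0), CG43074 (-1.92 ± 0.56), del (-0.81 ± 0.24) and CG9799 (-0.55 ± 0.17). CG43074, a transcript high in females, stood at 7.36 in control array 3, which carried female transcripts, and at 5.601 in control array 2, and changed by -0.97 without the pair numbered 3. The replicate block and the other settings run also called 0, and the compared groups alone with the block called 0 with 604 and 573 genes at unadjusted p under 0.05. Within batch 1, which held 2 F2 female arrays of each group, 0 genes were called (525 unadjusted), and within batch 2 for males 0 (50), but 2 against 2 arrays leave little power for a call. The 95% intervals of the fit that ignores the pairing reached to either side by a median of 0.625 log2 in females and 0.462 in males. They do not measure the precision of differences within pairs. In simulated data with independent noise 77.3% and 93.9% of genes changed by 2 log2 units were recovered, and 4.48% and 20.9% of those changed by 0.5.

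Several lists leaned together in F2 without any called member, 5 called in females and 8 in males at the preset correlation and 0 in either sex with an estimated one. In females oxidative phosphorylation genes had 11 of 71 positive and a median of -0.09, 0 called and 0 adjusted over the list alone (camera adjusted p = 2.9e-10, and 0.724 with an estimated correlation). Yolk, eggshell and ovary genes had 33 of 37 positive with 0 called (4.1e-12, and 0.665 with an estimated correlation), the piRNA pathway 30 of 32 (0.00455, and 0.944 with an estimated correlation) and heat shock genes 4 of 10 (0.0396, and 0.288 with an estimated correlation, 0.0966 with the replicate block). Accessory gland genes, the other list called, had 15 of 31 positive (0.00274, and 0.566 with an estimated correlation). Without the pair numbered 2, yolk had adjusted p = 0.913, the piRNA pathway 0.919 and heat shock 0.541, and only oxidative phosphorylation was called. In males accessory gland genes had 35 of 36 positive and a median of 0.24 with 0 called (4.7e-07, and 0.631 with an estimated correlation), and insulin and TOR signalling had 3 of 17 positive, 0 called (0.00241, and 0.48 with an estimated correlation). Yolk, eggshell and ovary genes had 1 of 21 positive, 0 called (2.7e-23, and 0.0945 with an estimated correlation). The piRNA pathway, detoxification, Polycomb with trithorax, digestive enzymes and oxidative phosphorylation were called too (adjusted p from 5.2e-08 to 0.0147, and from 0.242 to 0.861 with an estimated correlation). Without the male pair numbered 3 only the accessory gland list was called, while insulin and TOR signalling had 0.0936 and yolk 0.997.

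In the next generation no gene was called either. F3 females had 0 calls in limma with 27 genes at unadjusted p under 0.05, and F3 males 0 with 54. These counts too lay far below a 0.05 share of the entries tested. Residuals of same-numbered test and control arrays correlated at 0.447 to 0.777 in F3 females and 0.335 to 0.493 in F3 males. The smallest p-values, all adjusted to 1, belonged in females to the DNA helicase gene Blm (0.69 ± 0.19), CG14837 (0.34 ± 0.10; its other probe set changed by 0), CG13563 (0.81 ± 0.28), hydra (-0.97 ± 0.40), the cuticle gene Pcp (-0.996 ± 0.42) and the gut protease gene Jon66Cii (-1.09 ± 0.46). In males they belonged to CG10505 (0.43 ± 0.13), CG31097 (0.29 ± 0.10), the short neuropeptide F receptor gene sNPF-R (0.54 ± 0.19), the cuticle gene Cpr56F (-0.55 ± 0.15), T3dh (-0.64 ± 0.18) and CG15022 (-0.49 ± 0.15). The replicate block called 0. The compared groups alone called 1 in females, CG17217 (-0.20, adjusted p = 0.0388, named after its value was seen), and 0 in males, and with the block 0 (907 and 954 unadjusted). Within batches 1 and 2 of the females, 2 arrays per group, 0 and 0 genes were called (419 and 674 unadjusted), and within batch 2 of the males 0 (709), with the same lack of power. The 95% intervals of the fit that ignores the pairing reached to either side by a median of 0.541 log2 in females and 0.462 in males. With independent noise, 84.8% and 89.4% of simulated changes of 2 log2 units were recovered. The lists leaned by small amounts, 11 called in females and 4 in males at the preset correlation and 0 with an estimated one. In F3 females muscle genes had 0 of 24 positive, 0 called, with a median of -0.16 (camera adjusted p = 0.000791, and 0.552 with an estimated correlation), the fat body 1 of 18 (9.6e-05 and 0.541) and ribosomal proteins 8 of 34 with a median of -0.03 (0.001 and 0.552). Oxidative phosphorylation, digestion, innate immunity, detoxification, neuropeptides, glycolysis and eye genes leaned downward as well and the piRNA pathway upward (from 8.5e-07 to 0.0156, and from 0.539 to 0.606). In F3 males lipid turnover had 23 of 28 positive, 0 called, and a median of 0.12 (0.0029 and 0.879), and the 3 Y-linked genes had a median of -0.36 with 0 called (0.0103 and 0.157). Test males carried the founder line's Y, so for these genes descent from ablated founders and a different Y cannot be told apart. Glycolysis and the fat body leaned upward as well (0.0206 and 0.0386, and 0.976 each with an estimated correlation).

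**Figure D4:**
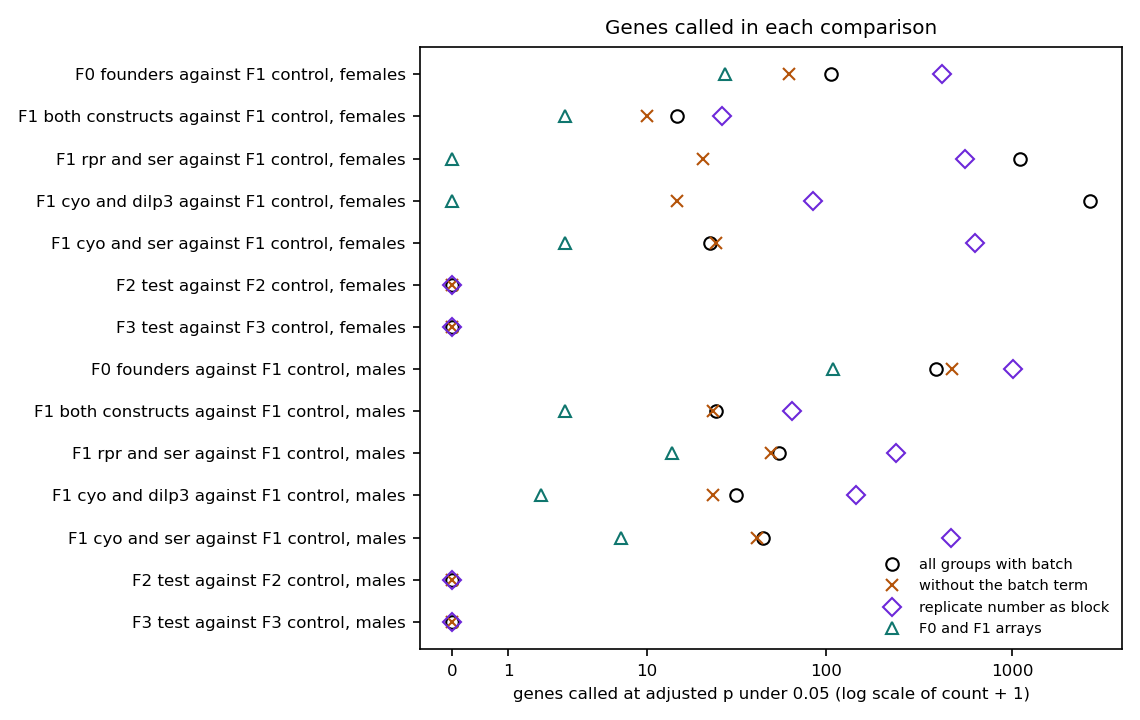
Number of genes called at an adjusted p under 0.05 in each comparison with all groups and batch, without the batch term, with F0 and F1 arrays only and with the replicate number as block. With all groups and batch the founder counts are 106 in females and 390 in males, and the F2 and F3 counts are 0 in each setting shown.

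The difference between the sexes in the effect of test descent called 0 genes in limma in F2 (20 at unadjusted p under 0.05) and 0 in F3 (19). In F3 the compared groups alone called 1, Hex-t1, a testis hexokinase gene (-0.62, adjusted p = 0.0136, named after its value was seen), and 1 gene was called without female test array 1 or 3.

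Founder changes were followed through the later generations. Of the 106 genes called in founder females, 98 (92.5%) changed in the same direction in F1 females with both constructs, by a median of 30.5% of the founder change, and of the 390 in males 345 (88.5%) by 30.2%. F1 siblings and founders share their control arrays, which by itself makes their changes agree in direction, and in siblings with cyo and ser, without driver or cell-death gene, the median was 45.3% and 44.0%. These percentages therefore do not measure founder change that was retained. In F2 54 of the 106 (50.9%) and 172 of the 390 (44.1%) kept the founder direction, with median changes in that direction of 0.00143 and -0.0131 log2. In F3 the numbers were 50 (47.2%) and 135 (34.6%), with medians of 0 and -0.0365.

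Fold changes across all genes tested were compared between generations. Genes are not independent replicates, so no p-value is given for these 6 correlations per sex. Between founders and F1 flies with both constructs Pearson's r was 0.493 in females and 0.466 in males (rho 0.414 and 0.411), against 0.509 and 0.534 simulated for the shared control arrays alone. Between F2 and F3, which share no labelled arrays but whose female arrays numbered 3 are nearly alike, r was 0.126 in females (rho 0.195, jackknife SE over arrays 0.66, and 0.0443 without the arrays numbered 3) and 0.0636 in males (rho 0.0618, SE 0.19). Founders correlated with F2 at 0.121 and -0.0717 and with F3 at -0.0788 and -0.123, with SEs from 0.13 to 0.45.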

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

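All tests of explanations in this part were chosen after the data were seen, among them F0 and F1 arrays only, separate batch numbers and both pairs left out, while the splits of the arrays were set before.

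Large counts in 3 female comparisons, with 1095 genes for rpr with ser, 2614 for cyo with dilp3 and 3982 for their interaction, rested on the batch term. The arrays of rpr with ser and of cyo with dilp3 shared no batch with the F1 control, so the fit linked them through arrays of other groups, among them the F2 female pair numbered 2 in batch 3. In that pair Yp1 stood at 9.203 (control) and 11.14 (test) and the eggshell gene Cp19 at 2.43 and 3.07.

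Of the genes called for the interaction, 18.7% had the fitted sign in all 3 differences taken within a replicate number. These differences were taken without the batch term, and arrays of the same number lay in different batches. The share therefore does not decide whether the genotypes are the source of the calls. It was not taken for rpr with ser or cyo with dilp3. Batches among the F0 and F1 arrays alone stay open. F0 and F1 arrays only with the batch term called 0 genes, at a lower precision (standard error 0.834 against 0.718). The genes called for the interaction had a smaller median absolute change there, 1.51 against 2.63, and 99.7% kept the fitted sign. Leaving out only the F2 female pair numbered 2 gave a median of 1.53 at a standard error of 0.691. The F2 pair is a candidate explanation for part of the calls, but 663 genes were still called for the interaction without it, and the design does not decide between a batch number that means different things in the F0 and F1 and the F2 and F3 arrays (708 with separate numbers) and other structure.

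Yolk, eggshell and ovary genes were lower in F2 test than in F2 control males, with a median change of -1.36. The mean yolk protein level of F2 male control array 3 was 12.54, against 2.86 to 3.17 in the other 3 arrays of the group, and its median level of the yolk, eggshell and ovary list was 8.19, against 2.42 to 2.43.

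Of 68 genes high in F2 and F3 females and low in the other F2 and F3 males, 97.1% (66) exceeded 3 log2 in this array, among them Yp2 (12.69), Yp3 (12.85), Cp36 (11.33) and osk (10.21). A female array under a male label was argued against, because the testis list had a median of 8.89 there, within the 8.43 to 9.38 of the other F2 male arrays. Descent from the founders was argued against as well, because without the pair numbered 3 the median change of the list was -0.00371 (adjusted p = 0.997). RNA of females in this 1 sample, at a median of 5.67% of the female level (quartiles 3.33% and 12.9%), is consistent with the values and stays open as a hypothesis. How it arose was not tested.

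Other arrays stood apart from the rest of their group of 4 by smaller amounts. The median level of the yolk, eggshell and ovary list was 2.42 in F2 male test array 2 against 2.43 in the other arrays. In F3 male test array 1, 5386 probe sets lay at the lowest value, against 5260 to 5272. Ilp2 was 3.72 in F3 female control array 2 (others 3.13 to 3.15). Ilp5 was 2.44 in F3 female test array 2 (others 2.35) and 2.99 in F3 female control array 2 (others 2.35 to 2.44). CG31041 was 3.38 in F2 male control array 1 (others 2.23 to 2.33), CG10505 was 2.76 in F3 male control array 2 (others 2.61 to 2.62) and Cpr56F was 2.49 in F3 male test array 3 (others 2.26 to 2.30). With the pair of values of F2 male control array 3 above, 10 of 84 sets of 4 values held such an array. Chance gives about 1 in 20 for independent values of normal spread. Several of these sets lie near the floor with nearly equal values, and sets share arrays. That rate therefore does not apply directly, and an excess of such arrays is not shown.

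The founder effect differed between the sexes in these genes, by limma's test of the difference itself (male minus female, n = 3 arrays per group). Ser12 differed by -6.08 (adjusted p = 1.4e-06), CG43074 by 4.38 (0.032), CG8654 by 3.01 (0.000157), CG12692 by -4.73 (1.1e-05), CG15239 by 3.56 (5.3e-12) and COX6AL2 by -2.67 (3.1e-07). CG43074 lay at 2.76 in control males and 10.40 in control females and CG12692 at 6.92 and 2.25, so these differences rest on genes near the floor in 1 sex. With both constructs in F1, Ser12 differed by -4.76 (0.00104), Atg5 by -2.50 (0.00106), plum by -2.29, Cyp310a1 by 1.64 and CG4988 by -1.46 (each 0.0469). F1 test females carried a founder X and F1 test males did not, so these differences by themselves do not tell constructs and X apart. Atg5 was also called in females with cyo and ser, which carry neither construct, so its rise did not need them. Ser12 lay at 2.53, 2.23 and 2.23 in females with cyo and dilp3, which carry a founder X too. The X alone therefore did not raise Ser12 there. For plum, Cyp310a1 and CG4988 constructs and X were not told apart. Ser12 and CG15239 of the founder set were called in all alternatives run (adjusted p at most 0.00774 and 0.00988), while CG4988 was called in 10 of 23 (0.00815 to 1).

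The arrays of each comparison were split in other ways to count how often as many genes are called. With 3 arrays per group there are 10 splits, too few to show a share under 0.05. For F0 females the real split called 106 genes and the highest other 1039, so that 2 of the 10 called as many. The higher split set F0 array 2 with control arrays 1 and 3 against the rest, which points to a structure of the samples other than the groups. The remaining comparisons of 3 with 3, except F2 females, had the most genes in the real split, 1 of 10. In females these were F1 with both constructs (15, highest other 14), rpr with ser (1095, 349), cyo with dilp3 (2614, 51) and cyo with ser (23, 10). In males they were F0 (390, 50), both constructs (25, 2), rpr with ser (55, 22), cyo with dilp3 (32, 9) and cyo with ser (45, 5). Compared only with the splits that part as many same-numbered pairs, 4 in each case, the highest others were 1039, 1, 349, 2 and 3 in females and 0 in males with rpr and ser, cyo and dilp3, and cyo and ser. F2 females called 0 in the real split and at most 2 in another (10 of 10 as many, which a real count of 0 fixes in advance).

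Where more splits exist, chance could be weighed for real counts above 0, although the 100 splits drawn for interactions and sex differences ignore the pairing of arrays by number. With a real count of 0 every split calls as many, so the shares given for such comparisons carry no information. The female interaction was reached by 1 of 100 splits, the real one (3982, highest other 2189), a share under 0.05, and the high count of another split points to a structure of the samples. The male interaction called 0 and other splits up to 407 (100 of 100 as many). F2 males called 0 and other splits up to 964 (35 of 35 as many), and that split set pairs 1 and 2 against pairs 3 and 4, while splits parting all pairs called at most 1. In F3 females and males no split called a gene (35 of 35 each). The sex difference of the founder effect called 16, and 20 of 100 splits called as many (highest 405), and that of both constructs 8, with 7 of 100 (highest 37), so these splits, which ignore the pairing, do not exclude chance for either count. In F2 and F3 the sex differences called 0, with 3125 and 2 as the highest other (100 of 100 each).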

How the results depend on the processing

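Among the alternatives below, F0 and F1 arrays only, separate batch numbers for each set of arrays, the F2 female pair numbered 2 left out, the F2 male pair numbered 3 left out, the F2 and F3 arrays numbered 3 left out and the block within F2 or F3 alone were chosen after the results they measure were seen, and the others before.

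A count is taken here as unchanged within 1.5-fold, a correlation within its standard error and a gene result while it stays on the same side of the threshold, so that a value can move without a change being recorded. Counts and correlations stayed the same in 295 of the comparisons with an alternative set beforehand, were weaker in 72 and stronger in 36. Of the gene results 2214 stayed, 397 were weaker, 1 was stronger and 7 reversed. With the alternatives added later 79 counts stayed, 28 were weaker and 7 stronger, and 414 gene results stayed and 124 were weaker. The gene results in both tallies include genes not called to begin with, among them Ilp2, Ilp5 and the genes named as not passing. Such genes stay unless they become called, so the tallies overstate how well calls held. Comparisons without a call enter the counts in the same way. Where a result changed, the cause was not tested unless stated.

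Without the batch term, the female counts fell from 106 to 63 in the founders, from 1095 to 21 with rpr and ser, from 2614 to 15 with cyo and dilp3 and from 3982 to 0 for the interaction. Of the genes called without it for rpr with ser, 19 of 21 were among the 1095. Cp19 (0.98), Cp16 (1.64) and Cp18 (2.17) reversed in the interaction without the term and, with the same values, when only the groups compared were fitted.

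The replicate block with batch raised the female counts of the founders to 418, of both constructs from 15 to 27 and of cyo with ser from 23 to 632. It lowered those of rpr with ser to 558, of cyo with dilp3 to 85 and of the interaction to 41, and few genes were shared with the fit without the block (31 of 558, 19 of 85 and 5 of 41). Cap-D2 reversed with cyo and dilp3, from 4.46 to -0.37 (adjusted p = 0.941). In males the block gave 1005 genes in the founders against 390, of which 375 were shared, 65 with both constructs against 25, 238 with rpr and ser against 55, 145 with cyo and dilp3 against 32, 470 with cyo and ser against 45 and 9 for the interaction against 0. Replicate numbers paired the arrays unevenly in male founders and in males with both constructs. Residuals of pairs 1, 2 and 3 correlated at 0.539, -0.0695 and 0.126 in the founders. With both constructs they correlated at 0.538, 0.199 and 0.00271. Whether a block by number is apt for these comparisons stays uncertain. The sex difference rose from 16 to 79 in the founders and from 8 to 14 with both constructs. The block changed no other count of genes.

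Only the groups compared, fitted without a batch term, leave few residual degrees of freedom. They called 1 gene in founder females, 1 with rpr and ser and 0 with both constructs, with cyo and dilp3, with cyo and ser and for the interaction. In males they called 49 in the founders and 0 in each F1 comparison with the control. Sex differences numbered 8 in the founders and 0 with both constructs. In F3 they called 1 gene in females and 1 for the sex difference, against 0.

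Filter, normalization and choice of probe sets moved few counts. For cyo with ser in females 55 genes were called without a filter and 36 with quantile normalization. The sex difference with both constructs was 4 with quantile normalization and 4 with every probe set tested. With both sexes in 1 fit the female counts were 202 in the founders, 27 with both constructs, 67 with rpr and ser, 30 with cyo and dilp3, 74 with cyo and ser and 4 for the interaction, and in males rpr with ser had 33.

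F0 and F1 arrays only, with the batch term, estimated the changes less precisely, and in females some changes were also smaller. For the genes called with all arrays, the median absolute change was 1.07 against 1.62 with rpr and ser (median standard error 0.517 against 0.417). It was 0.902 against 1.61 with cyo and dilp3 (0.519 against 0.44) and 1.51 against 2.63 for the interaction (0.834 against 0.718). F0 and F1 arrays only called 28 genes in founder females, 3 with both constructs, 0 with rpr and ser, 0 with cyo and dilp3, 3 with cyo and ser and 0 for the interaction. In males they called 109 in the founders (98 of them among the 390), 3 with both constructs, 14 with rpr and ser, 2 with cyo and dilp3 and 7 with cyo and ser, and 5 for the sex difference with both constructs. Separate batch numbers gave, in females, 169, 33, 68, 220 and 73 in the same order of founders and siblings, 708 for the interaction, and 5 for the sex difference with both constructs. The F2 female pair numbered 2 left out gave 24 with both constructs, 75 with rpr and ser, 221 with cyo and dilp3, 48 with cyo and ser and 663 for the interaction, of which 622 were among the 3982. The F2 male pair numbered 3 left out gave 15 with cyo and dilp3, 28 with cyo and ser and 5 for the sex difference with both constructs.

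Leaving out 1 array moved most counts that were not 0. In females the founder count was 59 without control array 3 and 165 without founder array 3. With both constructs it was 3 and 7 without test arrays 1 and 2 and at most 22 (without control array 2), with rpr and ser 1846 and 155 without control arrays 1 and 2, with cyo and dilp3 3478 and 729 without control arrays 1 and 2 and 1448 without sibling array 3, and with cyo and ser 46 and 72 without sibling arrays 2 and 3 and 14 without control array 3. In males the founder count was 251 without founder array 3 and 231 and 235 without control arrays 1 and 2. With both constructs it was 10, 17 and 2 without test arrays 1, 2 and 3, and 13 and 12 without control arrays 2 and 3. With rpr and ser it was 28 without sibling array 2 or control array 3. With cyo and dilp3 it was 22, 12 and 3 without sibling arrays 1, 2 and 3, 15 without control array 1 and 9 without control array 2 or 3. With cyo and ser it was 26 and 16 without control arrays 1 and 3 and 53 without sibling array 3. The sex difference of the founder effect was 25 without male founder array 1 or female control array 1 and 31 without female founder array 2 or 3. With both constructs it was 5 without male test array 2 or female test array 1 or 2, and 4 without male test array 3 or male control array 3. In F3 it was 1 without female test array 1 or 3. Ilp5 was called once, in the female interaction without cyo and ser array 2 (2.19, adjusted p = 0.0155), at levels near the floor.

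Gene lists were called only with the preset correlation. With an estimated correlation 0 lists were called in all 16 comparisons. With the preset value the numbers were, in females, 4 in the founders, 4 with both constructs, 9 with rpr and ser, 11 with cyo and dilp3, 3 with cyo and ser, 12 for the interaction, 5 in F2 and 11 in F3, and in males, in the same order, 1, 1, 6, 4, 2, 5, 8 and 4. With the replicate block founder females had 2 and females with cyo and ser 6, founder males 4, males with both constructs 2, males with cyo and ser 5 and the male interaction 2. The numbers for rpr with ser in females hid reversals, since detoxification, piRNA, muscle and Polycomb genes were called in the opposite direction with the block (adjusted p = 0.0325, 0.000485, 0.00069 and 0.000172). Without the F2 female pair numbered 2 the lists were 2 in founder females, 8 with both constructs, 4 with rpr and ser, 6 with cyo and dilp3 and 1 in F2. Without the F2 male pair numbered 3 they were 3 with both constructs, 2 for the interaction and 1 in F2.

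Chromosome arms with more called genes than chance numbered 1 in founder males and 1 in males with cyo and dilp3. With the replicate block, arms 2L and 2R held more in males with cyo and dilp3 (Fisher's exact test, adjusted p = 0.00195 and 0.0259). In founder males 2L no longer passed with the block (0.233). The X chromosome held fewer called genes than chance with the block in founder males (adjusted p = 0.0137). It also held fewer in F1 males with both constructs (0.000869), rpr and ser (0.000306), cyo and dilp3 (0.00023) and cyo and ser (0.00792).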

Other observations

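The contrast between siblings and its chromosome shares were added after the comparisons with the control were seen, and the tests of sequence variants under the probes after the shares were seen.

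Genes called between F1 siblings without the replicate block lay mostly on the chromosome that the siblings inherited in different forms. For rpr against cyo, on the second chromosome, the share was 94.7% of called genes in males and 91.7% in females, and for dilp3 against ser, on the third, 88.5% and 100%. Variants on the inherited chromosomes that act on genes nearby may explain this, and each share exceeded that of all genes tested by Fisher's exact test (adjusted p at most 6.6e-07). Sequence variants that change probe binding but not expression stay open. Of the well expressed called genes 13.5% (7 of 52) in males and 26.3% (5 of 19) in females differed by more than 1 log2 unit beyond their error, but this does not decide, since how well the shared w1118 allele binds the probes is not known. With the replicate block 799 and 1955 genes were called between dilp3 and ser siblings and the shares on chromosome 3 were 57.9% and 47.7%. Whether inversions of the balancers, linked variants of the lines or the inserted constructs act on these genes was not tested.

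Genes behind these shares, chosen after their values were seen, include on the second chromosome lectin-33A (1.67 higher with rpr in females), CG8654 (1.5, females) and CG31809 (2.80, males), and on the third CG13032 (2.93 higher with dilp3 in females) and ms(3)76Ba (-2.36, females).

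The female arrays numbered 3 of F2 and F3 were closer to each other than any other arrays of the study. The root mean square difference over all entries was 0.140 log2 between the F2 and F3 test arrays numbered 3 and 0.144 between the control arrays numbered 3, although they belong to different generations. The next closest arrays, F2 control and test numbered 1, differed by 0.190. Arrays of the same number resembled each other within F2 and F3, with a mean correlation of their residuals of 0.944 in F2 females, 0.662 in F3 females, 0.694 in F2 males and 0.412 in F3 males, against 0.542 and 0.328 in the F0 and F1 arrays of females and males.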
